A study of Mus musculus with 9 samples.

How the data were processed

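Gene expression was measured by RNA sequencing of cultured cancer-associated fibroblasts. Per the labels, total RNA was extracted from cells grown in medium with fetal bovine serum, and strand-specific libraries were made with the dUTP method. The deposited table holds 1 whole-number read count per gene and library, with 9 columns that were each matched to a sample by name and sum to 18199957 to 25238624 counts. Per the submitters' processing notes, reads were trimmed with fastp, aligned to the mouse genome build mm10 with HISAT2 2.2.1 and counted with featureCounts 2.0.6, and the authors ran DESeq2 1.42.0. The order and settings of those steps, the annotation release and the strand setting of the counting are not given in the sources used here. Whether reads from antisense neighbours were kept apart is therefore unknown, and genes with an annotated overlap are uncertain: among the genes named these include Dio2, Thra, Ddit3, Cxcl10, Ccnd1, Foxm1, Acss2, Cyp51, Shisa3 and Col3a1. Genes with close paralogs, such as Hsd3b6, Acot2, Oasl2, Ly6a, Scd1, Scd2 and the keratins, are uncertain in the same way, since the handling of reads that align to several places is not given either.

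The table lists 54532 Ensembl gene identifiers, and 54409 of them were matched to a symbol in GENCODE M21, whose mm10 coordinates are used. The other 123 identifiers held 0.0221% to 0.0289% of a library's counts and stayed in the tests under their identifiers. No normalised values were taken from the authors: the counts were used as deposited. CPM values, counts scaled to a common library size, were computed with trimmed-mean (TMM) factors, and errors of group means are standard deviations over 3 libraries.

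The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), fitted to all 9 libraries with 1 mean per group, TMM factors and edgeR's filter on low counts, which kept 15276 genes. The groups thus shared 1 estimate of the spread, a biological coefficient of variation of 0.159. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and the errors of log2 fold changes are standard errors from that fit. On simulated counts for the same 15276 genes with 200 genes changed, the test recovered 64% of 2-fold and 90% of 4-fold changes for KO versus WT, 74% and 89% for KO+T3 versus KO, and 54% and 89% for KO+T3 versus WT. Of its calls there, 5.52%, 3.55% and 2.72% were false. In the data themselves 69%, 30.5% and 65.6% of genes were called, far more than the 200 simulated. These rates may therefore not carry over to the tests below. Where a group had 0 counts, the fold change is given as a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts, as a ratio with its 95% counting interval. Floors and intervals cover counting error only.

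Before the data were examined, 40 gene lists were written from textbook knowledge: 31 on fibroblast biology, signalling and metabolism, 8 with markers of other cell types and 1 of sex-linked genes. They hold 687 entries, of which 1 was not matched to a symbol. Lists with at least 5 measured members, 37 in all, were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and again with a correlation estimated from the residuals, with adjustment over the lists in each comparison. Members called were counted over all genes tested and also adjusted over the list alone.

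The rule for the genes named was fixed at the same time. It takes Dio1, Dio2, Dio3, Thra, Thrb, Klf9 and Hr in every comparison where they were measured. In KO versus WT and in KO+T3 versus KO it takes the 6 called genes with the highest and the 6 with the lowest log2 fold change. These needed a mean of at least 100 counts over the 6 libraries compared and groups that did not overlap, and predicted genes and pseudogenes were passed over. It adds the 3 called members with the lowest adjusted p from each biology list with at least 3 called members. Where more than 8 lists had so many, the 8 with the highest share of called members were used. For KO+T3 versus WT it takes the 3 genes at each end, and among genes reversed with T3 the 4 that were lowest and the 4 that were highest in KO. From lists of other cell types and of sex-linked genes it takes the 2 members with the highest mean CPM. Other genes named were chosen after their values were seen. This is said where they appear, apart from members named to spell out a list count, such as Actg2, Acacb, Atf3, Gpd2, Me1 and Cpt1a.

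Reversal was counted over genes called in KO versus WT as genes called in the opposite direction in KO+T3 versus KO. Both comparisons share the KO libraries, which gives opposite signs by chance, so 50 sets of negative binomial counts were drawn in which T3 had no effect.

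The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, 3 other scalings, 2 other filters on low counts, a fit of the 2 groups alone, a replicate block, a 2-fold threshold and leaving out each library. Other alternatives were added after the data were seen: WT represented by replicate 1 alone, with the spread taken from the other groups, and removal of each library's smooth trend on GC content and transcript length, taken from the longest annotated transcript of 99.9% of the tested genes. No library was left out of the values reported.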

Results

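Gene expression was measured in cultured cancer-associated fibroblasts of mice, from a series on cutaneous squamous cell carcinoma. The enzyme under study is type 2 deiodinase, encoded by Dio2, which converts thyroxine into the active thyroid hormone T3. The 9 libraries form 3 groups of 3. WT cells carried a Col1a2-driven Cre recombinase and intact Dio2 alleles, and KO cells carried the recombinase and floxed Dio2 alleles. The libraries labelled KO+T3 came from KO cells given 30 nM T3 for 48 h, and are called KO+T3 from here on. No vehicle or treatment time is given for the KO and WT libraries. Changes described as with T3 may therefore include differences of culture or harvest. Total counts were 22138443, 18199957 and 20575933 in WT, 18334783, 23607078 and 19508278 in KO, and 25238624, 20361940 and 20896025 in KO+T3. The series calls the replicates biological, but the labels do not say whether they were separate cultures or animals. The p-values therefore measure only the spread between these libraries, which may be technical in KO and KO+T3.

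Libraries of a group lay close together, and WT lay apart from both other groups along the first principal component, which held 74.6% of the variance of log2 CPM. The second held 11.7% and parted KO from KO+T3. The 10 most abundant genes took 11.9% to 12.4% of the counts in WT, 4.63% to 4.95% in KO and 5.16% to 5.42% in KO+T3. WT replicate 1 stood apart from the rest of its group. It had 10786 counts of Xist, which is transcribed from the inactive X chromosome of female cells, and 0 counts of the Y-linked genes Ddx3y and Eif2s3y. Every other library had 0 to 3 counts of Xist and 728 to 2865 counts of Ddx3y. No label gives the sex of the animals, but by these counts the WT libraries came from cells of both sexes. The spread within WT is therefore not technical alone. In KO+T3, replicate 1 held 34 CPM of Ddx3y against 86.2 and 104 in KO+T3 replicates 2 and 3. Eif2s3y stood at 44.8 CPM there against 72.2 and 75.4. The spread within KO+T3 may therefore not be technical alone either, and the cause was not tested.

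**Figure D1:**
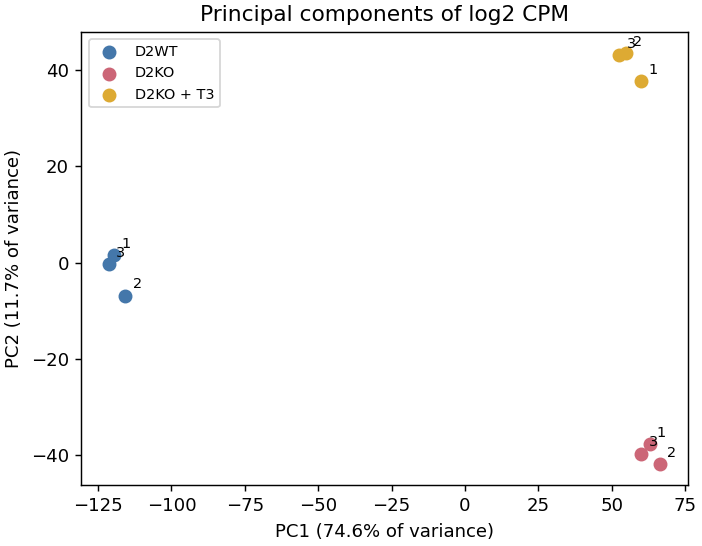
Position of each of the 9 libraries on the first 2 principal components of log2 CPM, which hold 74.6% and 11.7% of the variance. Each point is 1 library, coloured by group, and the WT libraries lie apart from KO and KO+T3 on the first component.

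Dio2 (ENSMUSG00000007682, chromosome 12, 90724552 to 90738438 in mm10) had 56, 67 and 84 counts in the WT libraries and 16, 25 and 18 in the KO libraries. Its level was 3.77 ± 0.856 CPM in WT and 0.866 ± 0.0860 CPM in KO (SD, n = 3), a log2 fold change of -2.11 (SE 0.323; edgeR adjusted p = 1.12e-04). The libraries labelled KO+T3 had 49, 74 and 46 counts, or 2.60 ± 0.938 CPM, which was higher than in KO by 1.57 on the log2 scale (SE 0.324; edgeR adjusted p = 3.79e-03). Against WT, the change in KO+T3 was -0.54 (edgeR adjusted p = 0.126), and 1 library decided that call: it was -0.72 without WT replicate 1 (edgeR adjusted p = 0.0468) and -0.85 without KO+T3 replicate 2 (edgeR adjusted p = 0.0336). The labels do not say which exons are floxed, so a count over the whole gene may hold reads from exons outside the deleted part, and reads of the antisense gene Gm26512 could not be set apart.

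Other genes of thyroid hormone action also differed between the groups. Dio3, the deiodinase that inactivates T3, stood at 22.7 ± 2.39 CPM in WT, 0.508 ± 0.469 in KO and 4.80 ± 0.938 in KO+T3 (SD, n = 3). Its log2 fold change was -5.42 in KO (SE 0.483; edgeR adjusted p = 1.43e-06) and 3.18 with T3 (SE 0.493; edgeR adjusted p = 6.26e-04). KO replicate 2 held 24 of its counts against 12 and 0 in the rest of the group, and without that library the values were -6.25 and 4.02. Thrb, a thyroid hormone receptor, rose by 0.88 in KO (edgeR adjusted p = 8.50e-04) and by a further 0.79 with T3 (edgeR adjusted p = 4.00e-03). Thra, the other receptor, changed by -0.11 in KO (edgeR adjusted p = 0.350), and fell by 0.46 with T3 (edgeR adjusted p = 6.44e-03). Klf9, a transcription factor induced by T3, rose from 29.0 ± 2.58 CPM in WT to 41.0 ± 5.12 in KO and 71.2 ± 3.93 in KO+T3, log2 changes of 0.50 (edgeR adjusted p = 2.61e-03) and 0.80 (edgeR adjusted p = 4.22e-04). The rise of Klf9 in KO was not called against WT replicate 1 alone (edgeR adjusted p = 0.0513). Hr, a corepressor gene that also responds to T3, changed by 0.06 in KO (edgeR adjusted p = 0.855) and rose by 1.12 with T3 (edgeR adjusted p = 7.10e-03). With the trends on GC content and transcript length removed, Thra and Hr were called lower in KO, at -0.82 and -1.28 (edgeR adjusted p = 1.81e-05 and 2.37e-03). Dio1 had 0 counts in every library.

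**Figure D2:**
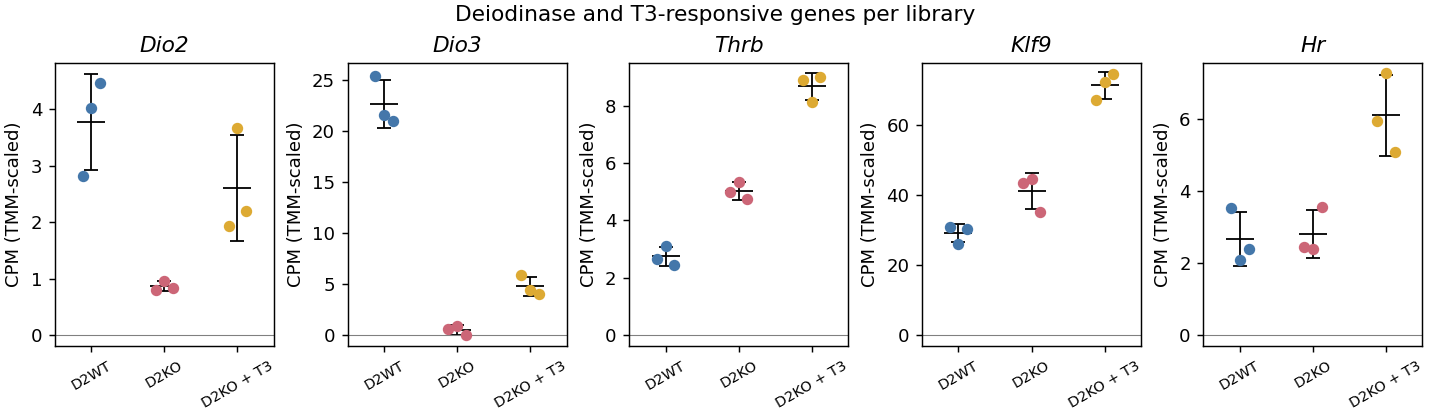
Level of Dio2, Dio3, Thrb, Klf9 and Hr in CPM scaled with TMM factors. Each point is 1 library, with the mean and SD of the 3 libraries of a group. Dio2 lay at 0.799 to 0.963 CPM in KO and at 1.93 to 3.67 CPM in KO+T3.

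The comparison of KO with WT asks what differed between fibroblasts with floxed and with intact Dio2. Transcripts of the interferon response, of inflammatory secretion and of the collagen matrix were much lower in KO, and transcripts of the cell division machinery were higher. Keratinocyte and myeloid markers moved with them, and none of these lists held its call with an estimated correlation (camera adjusted p = 0.0833, 0.414, 0.152 and 0.467 for interferon, inflammatory, collagen and cell cycle genes). Col3a1, the chain of type III collagen, stood at 264 ± 26.3 CPM in KO and 18430 ± 1853 in WT (SD, n = 3), a log2 fold change of -6.12 (SE 0.147; edgeR adjusted p = 1.89e-10). Isg15, an interferon-induced ubiquitin-like protein, stood at 3.99 ± 0.692 CPM in KO and 299 ± 81.0 in WT, a change of -6.23 (SE 0.228; edgeR adjusted p = 2.21e-09). Ccnd1, which encodes cyclin D1, stood at 522 ± 23.8 CPM in KO and 23.2 ± 6.43 in WT, a change of 4.49 (SE 0.188; edgeR adjusted p = 4.66e-09).

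All 27 measured interferon-stimulated genes were lower in KO, with a median log2 fold change of -5.36. Cxcl10, a chemokine, fell by 6.46 (edgeR adjusted p = 7.56e-10), and Oasl2, an antiviral protein of the oligoadenylate synthetase family, by 6.67 (edgeR adjusted p = 8.91e-10). The list was lower as a set (camera adjusted p = 6.54e-37, and adjusted p = 0.0833 with an estimated correlation). Of 7 measured genes of antigen-presenting fibroblasts, 6 were lower and 0 higher, with a median of -4.04 (camera adjusted p = 0.006, and adjusted p = 0.137 with an estimated correlation), and without WT replicate 1 the median was -3.07, with 1 higher. It was -3.40 with the trends on GC content and length removed. Cd74 and H2-Eb1, of the class II antigen presentation machinery, were among them at -4.40 and -4.82, named after their values were seen.

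Inflammatory fibroblast genes were lower for 17 of 21 measured members, with a median of -3.47 (camera adjusted p = 8.88e-06, and adjusted p = 0.414 with an estimated correlation). Il33, an alarmin cytokine, fell by 3.58 (edgeR adjusted p = 2.41e-09) and the complement gene C4b by 3.47 (edgeR adjusted p = 8.84e-09). The members that were higher were Csf1, a growth factor for macrophages, at 2.36 (edgeR adjusted p = 1.85e-08), and the cytokine Il11 at 2.04 (edgeR adjusted p = 1.88e-04). Saa3, an acute phase protein, had the lowest fold change at -15.03 (edgeR adjusted p = 5.36e-06). WT replicate 1 held 11000 CPM of Saa3 against 687 and 787 in WT replicates 2 and 3, and without it the change was -12.54. The iron-binding protein gene Lcn2 had 0 counts in KO and was at least 852-fold lower there than in WT (edgeR adjusted p = 7.04e-04). That bound is carried by WT replicate 1, which held 95.5 CPM of Lcn2 against 4.92 and 6.07 in WT replicates 2 and 3. Il6 and Cxcl5 were also several times higher in WT replicate 1, and their changes of -8.94 and -9.29 (edgeR adjusted p = 3.69e-07 and 7.45e-08) were -8.01 and -8.41 without it. Steap4, a metalloreductase, also had 0 counts in KO and was at least 496-fold lower (edgeR adjusted p = 6.05e-07).

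Collagen and matrix transcripts were lower on most lists. Of 17 interstitial collagens, 13 were lower and 3 higher, with a median of -1.89 (camera adjusted p = 6.92e-07, and adjusted p = 0.152 with an estimated correlation). With the trends on GC content and length removed, 15 were lower and 2 higher, with a median of -2.87. Col1a2 fell by 3.31 (edgeR adjusted p = 3.24e-09) and Col12a1 by 3.34 (edgeR adjusted p = 8.39e-09). The higher members were Col5a3, Col10a1 and Col15a1, named after their values were seen. Matrix glycoproteins and proteoglycans were lower for 20 of 26 and higher for 3, with a median of -1.65 (camera adjusted p = 3.04e-09). This was the only list of the 37 tested whose call held with an estimated correlation (adjusted p = 0.0489 with an estimated correlation). The small proteoglycans Lum and Ogn, which bind collagen fibrils, changed by -10.94 (edgeR adjusted p = 5.31e-09) and -9.56 (edgeR adjusted p = 2.41e-09). Collagen processing and crosslinking genes were lower for 13 of 17 and higher for 2, with a median of -0.93 (camera adjusted p = 7.23e-04, and adjusted p = 0.219 with an estimated correlation). Myofibroblast and contractile genes were lower for 13 of 20 and higher for 2, Actg2 and Lmod1, with a median of -1.24 (camera adjusted p = 1.22e-06, and adjusted p = 0.0567 with an estimated correlation). Dermal fibroblast identity genes were lower for 15 of 21 and higher for 4, with a median of -1.07 (camera adjusted p = 0.0394, and adjusted p = 0.414 with an estimated correlation). Among them, the receptor gene Pdgfra fell by 1.90 (edgeR adjusted p = 3.61e-08) and the surface antigen Ly6a by 2.88 (edgeR adjusted p = 6.97e-08), while Dlk1, a Notch ligand homolog, had the highest fold change among genes with a mean of at least 100 counts, at 7.05 (edgeR adjusted p = 8.41e-09). Without WT replicate 1 the change of Dlk1 was 7.75. The call of the identity list was lost in the fit of the 2 groups alone, with a replicate block and without KO replicate 3 (camera adjusted p = 0.0598, 0.0528 and 0.0661).

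Keratinocyte transcripts moved with these groups. Of 13 measured keratinocyte and squamous carcinoma markers, 11 were lower in KO and 0 higher, with a median of -4.19 (camera adjusted p = 3.26e-04, and adjusted p = 0.152 with an estimated correlation), or -5.09 with the trends on GC content and length removed. Krt14, a basal keratin, had 2226, 23411 and 24246 counts in WT replicates 1 to 3 and 35 to 89 in every other library. Krt5, its partner, had 439, 8179 and 8423 counts in WT and 1 to 9 elsewhere. The fall of Krt5, -11.33 by edgeR (adjusted p = 1.14e-05), was not called by limma-voom (adjusted p = 0.0768). Of 10 measured macrophage and myeloid markers, 8 were lower and 0 higher, with a median of -2.84 (camera adjusted p = 0.019, and adjusted p = 0.414 with an estimated correlation), and of -2.21 without WT replicate 1. Lyz2 stood at 109 to 151 CPM in WT and 9.79 to 12.3 CPM elsewhere. Without WT replicate 1, 27 interferon-stimulated genes, 13 collagens and 16 inflammatory genes were lower in KO, and against WT replicate 1 alone, with the spread taken from the other groups, these counts were 27, 13 and 18.

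Hypoxia-responsive genes were lower for 14 of 17 measured members and higher for 2, with a median of -1.87 (camera adjusted p = 2.41e-06, and adjusted p = 0.137 with an estimated correlation). Bnip3, a mitophagy receptor, fell by 3.30 (edgeR adjusted p = 1.72e-09), P4ha1, a collagen prolyl hydroxylase, by 2.39 (edgeR adjusted p = 2.55e-09) and Pdk1, which inhibits pyruvate dehydrogenase, by 4.11 (edgeR adjusted p = 1.62e-08). Glycolysis genes were lower for 11 of 19 and higher for 2, with a median of -0.56 (camera adjusted p = 2.69e-03, and adjusted p = 0.453 with an estimated correlation). Wnt pathway targets and antagonists were lower for 10 of 16 and higher for 4, with a median of -1.41 (camera adjusted p = 0.0182, and adjusted p = 0.152 with an estimated correlation). The members of the Wnt list that fell most were the secreted proteins Sfrp2 at -7.98 and Rspo3 at -5.87, an antagonist and an enhancer of Wnt signalling, named after their values were seen.

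Of 13 mitochondrially encoded genes, 11 were lower in KO and 0 higher, with a median of -0.82 (camera adjusted p = 0.0394, and adjusted p = 0.681 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were lower for 19 of 27 and higher for 3, with a median of -0.51 (camera adjusted p = 0.0391, and adjusted p = 0.759 with an estimated correlation). Both calls were lost without WT replicate 1 (camera adjusted p = 0.0598 for each) and without KO replicate 2 (camera adjusted p = 0.0508 for each). The fold changes followed GC content, from a median of -0.58 in the fifth of genes with the lowest GC content to 0.68 in the fifth with the highest, and with this trend and that on length removed, 7 mitochondrially encoded genes were higher in KO and 1 lower, and 9 oxidative phosphorylation genes were lower and 4 higher.

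Cell cycle genes were higher in KO for 26 of 28 measured members and lower for 0, with a median of 1.19 (camera adjusted p = 2.32e-06, and adjusted p = 0.467 with an estimated correlation). Foxm1, a transcription factor of the division cycle, rose by 3.15 (edgeR adjusted p = 2.27e-07) and Pcna, the sliding clamp of DNA polymerase, by 1.38 (edgeR adjusted p = 2.72e-07). Genes of p53 and senescence were higher for 13 of 20 and lower for 6, with a median of 0.91, and the list was not called (camera adjusted p = 0.0646). It was called without the low-count filter (camera adjusted p = 0.00264) and without WT replicate 2 or 3 or KO replicate 1 or 3 (camera adjusted p = 0.0366 to 0.0493), and its median was 0.33 with the trends on GC content and length removed. The p53 targets Mdm2 and Cdkn1a rose by 1.85 (edgeR adjusted p = 4.08e-08) and 1.89 (edgeR adjusted p = 5.08e-08), while the death receptor gene Fas fell by 3.60 (edgeR adjusted p = 2.56e-09). Of 10 Hedgehog pathway genes, 6 were lower and 3 higher (camera adjusted p = 0.478). Gas1, a Hedgehog co-receptor, fell by 4.46 (edgeR adjusted p = 2.10e-08) and the transducer Smo rose by 1.40 (edgeR adjusted p = 2.06e-07). Hhip, which binds Hedgehog ligands, had 3 counts over the WT libraries and was higher in KO by a ratio of 71.8 (95% counting interval 24.3 to 350; edgeR adjusted p = 1.29e-07).

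Among other genes at the upper end, Kif1a, an axonal transport motor, rose by 6.92 (edgeR adjusted p = 1.33e-10), the secreted peptide precursor Vgf by 6.55 (edgeR adjusted p = 5.75e-08), the pentraxin Nptx1 by 6.37 (edgeR adjusted p = 2.13e-09), the phosphatase Dusp4 by 5.98 (edgeR adjusted p = 2.55e-09) and the membrane protein gene Prrt4 by 5.93 (edgeR adjusted p = 2.10e-08). At the lower end, Shisa3 had 0 counts in KO and was at least 258-fold lower (edgeR adjusted p = 1.16e-03), though WT replicate 1 held 0.906 CPM against 16.8 and 17.9 in WT replicates 2 and 3, so the bound does not hold against that library.

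By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 10544 of 15276 tested genes (69%) differed between KO and WT, 5352 higher and 5192 lower, with a median absolute log2 fold change of 1.1. In 73.3% of genes the groups did not overlap, where chance gives 10%. Adjusted over the list alone, the counts of list members were the same except for 1 more higher member on the antigen-presenting, inflammatory, glycoprotein, protease, basement membrane and fatty acid synthesis lists and 1 more lower member on the oxidative phosphorylation list. Scaling by library totals moved the median of all genes from 0.0173 to 0.291 and the share of calls that were higher from 50.8% to 63.6%, so directions here are relative to that shift.

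**Figure D3:**
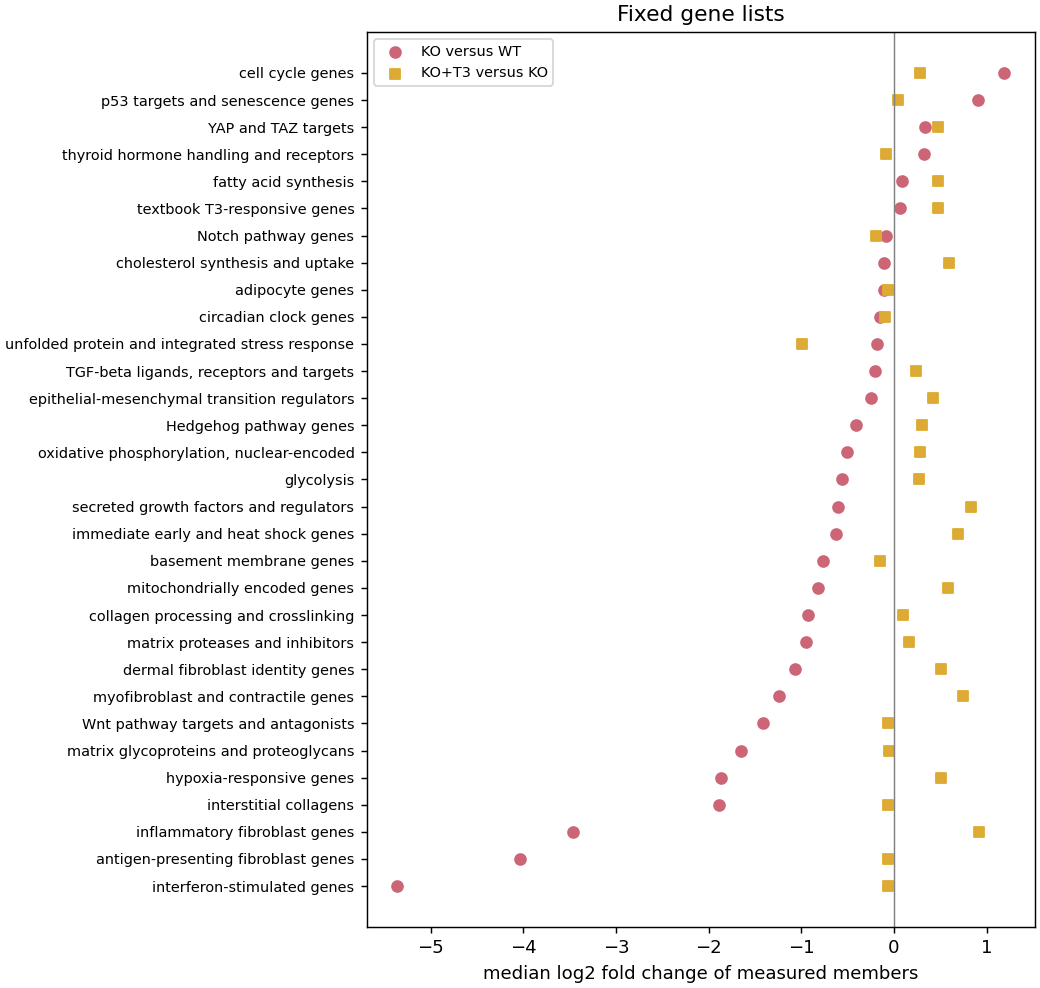
Median log2 fold change of the measured members of each of the 31 biology lists. Circles give KO versus WT and squares KO+T3 versus KO. Interferon-stimulated genes lie at -5.36 in KO and -0.07 with T3, and myofibroblast genes at -1.24 and 0.74.

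The comparison of KO+T3 with KO asks what differed between KO cells given T3 for 48 h and KO cells without a recorded treatment. The list of unfolded protein and integrated stress response genes was lower with T3, with members in both directions, while the lists of contractile genes, cholesterol genes and secreted factors were higher. None of these lists held its call with an estimated correlation (camera adjusted p = 0.0716, 0.07, 0.38 and 0.123). Trib3, a pseudokinase induced by the integrated stress response, fell from 125 ± 9.94 CPM in KO to 7.72 ± 0.243 in KO+T3 (SD, n = 3), a log2 fold change of -4.02 (SE 0.130; edgeR adjusted p = 9.04e-09). Thbs1, the matricellular protein thrombospondin 1, rose from 2355 ± 200.2 to 9267 ± 588 CPM, a change of 1.98 (SE 0.101; edgeR adjusted p = 4.02e-07). Il11 rose from 33.8 ± 3.29 to 495 ± 10.6 CPM, a change of 3.87 (SE 0.335; edgeR adjusted p = 1.02e-05).

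Of 19 measured genes of the unfolded protein and integrated stress responses, 11 were lower with T3 and 7 higher, with a median of -0.99 (camera adjusted p = 2.15e-12, and adjusted p = 0.0716 with an estimated correlation). The stress transcription factor gene Ddit3 fell by 2.85 (edgeR adjusted p = 2.55e-08) and Chac1, which degrades glutathione, by 3.83 (edgeR adjusted p = 4.07e-07). Atf4 at -1.22 and the serine and asparagine synthesis genes Asns at -1.57, Psat1 at -1.01 and Phgdh at -0.81 were also among the members that fell. The members that rose were Xbp1 at 0.94, a regulator of the unfolded protein response, and the chaperones and chaperone partners of the endoplasmic reticulum Hspa5, Hsp90b1, Calr, Pdia4, Creld2 and Sdf2l1, at 0.45 to 1.09. The members without an adjusted p were named after their values were seen, and no test compared those that fell with those that rose.

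Myofibroblast and contractile genes were higher with T3 for 14 of 20 measured members and lower for 0, with a median of 0.74 (camera adjusted p = 4.56e-08, and adjusted p = 0.07 with an estimated correlation). Tpm1, a tropomyosin, rose by 1.01 (edgeR adjusted p = 7.60e-06) and Lmod1, an actin nucleator of muscle, by 1.06 (edgeR adjusted p = 5.34e-05). Targets of YAP and TAZ were higher for 7 of 14 and lower for 2, with a median of 0.48 (camera adjusted p = 0.0173, and adjusted p = 0.636 with an estimated correlation). F3, which encodes tissue factor, rose by 2.30 (edgeR adjusted p = 1.10e-07) and the matricellular protein gene Ccn1 by 1.24 (edgeR adjusted p = 1.22e-05), while Amotl1, which binds YAP, fell by 0.70 (edgeR adjusted p = 1.18e-04). The YAP and TAZ call was lost without KO replicate 3 (camera adjusted p = 0.0689). TGF-beta ligands, receptors and targets were higher for 9 of 21 and lower for 1, with a median of 0.24 (camera adjusted p = 0.0118, and adjusted p = 0.606 with an estimated correlation). Dermal fibroblast identity genes were higher for 8 of 21 and lower for 1, with a median of 0.51 (camera adjusted p = 5.12e-03, and adjusted p = 0.38 with an estimated correlation). Pdgfra and Ly6a were among those that rose, by 0.56 and 0.76 (edgeR adjusted p = 1.90e-03 and 5.28e-03).

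Cholesterol synthesis and uptake genes were higher for 15 of 20 measured members and lower for 0, with a median of 0.59 (camera adjusted p = 4.56e-08, and adjusted p = 0.38 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, rose by 1.49 (edgeR adjusted p = 3.93e-05), the sterol demethylase Cyp51 by 1.09 (edgeR adjusted p = 4.26e-05) and the isomerase Idi1 by 1.91 (edgeR adjusted p = 5.56e-05). Fatty acid synthesis genes were higher for 7 of 13 and lower for 1, Acacb, with a median of 0.48 (camera adjusted p = 2.97e-03, and adjusted p = 0.536 with an estimated correlation). Scd1, a desaturase, rose by 1.21 (edgeR adjusted p = 3.31e-06), Scd2 by 1.57 (edgeR adjusted p = 1.97e-04) and Acss2, which activates acetate, by 1.60 (edgeR adjusted p = 1.19e-05). Mitochondrially encoded genes were higher for 10 of 13 and lower for 0, with a median of 0.58 (camera adjusted p = 3.37e-03, and adjusted p = 0.636 with an estimated correlation). Among them, mt-Nd1 rose by 0.89, mt-Co1 by 0.71 and mt-Nd2 by 0.63 (edgeR adjusted p = 3.64e-04, 3.05e-03 and 5.68e-03). Oxidative phosphorylation genes encoded in the nucleus were higher for 9 of 27 and lower for 0, with a median of 0.28 (camera adjusted p = 0.0118, and adjusted p = 0.655 with an estimated correlation). That call was lost without KO+T3 replicate 1 (camera adjusted p = 0.209). With the trends on GC content and length removed, 3 mitochondrially encoded genes and 4 oxidative phosphorylation genes were higher.

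Secreted growth factors and regulators were higher for 17 of 33 measured members and lower for 1, with a median of 0.83 (camera adjusted p = 1.64e-07, and adjusted p = 0.123 with an estimated correlation). Igfbp5 at 3.15 and Fgf2 at 2.47 were among them, named after their values were seen. Inflammatory fibroblast genes were higher for 9 of 21 and lower for 2, with a median of 0.92 (camera adjusted p = 2.97e-03, and adjusted p = 0.651 with an estimated correlation). Il6 rose by 4.54 (edgeR adjusted p = 5.52e-04) and the chemokine Cxcl5 by 4.38 (edgeR adjusted p = 5.38e-05). Of 10 macrophage and myeloid markers, 2 were also higher and 0 lower (camera adjusted p = 0.222). Immediate early and heat shock genes were higher for 10 of 17 and lower for 1, Atf3, with a median of 0.69 (camera adjusted p = 1.64e-04, and adjusted p = 0.636 with an estimated correlation). The nuclear receptor gene Nr4a1 rose by 3.47 (edgeR adjusted p = 5.45e-07), Ier3 by 2.02 (edgeR adjusted p = 8.01e-06) and Fos by 1.47 (edgeR adjusted p = 2.07e-04).

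Textbook T3-responsive genes were higher for 5 of 11 measured members and lower for 1, with a median of 0.48 (camera adjusted p = 0.0118, and adjusted p = 0.536 with an estimated correlation). Klf9, Hr, Dio3, Gpd2 and Me1 rose and Cpt1a fell. Circadian clock genes were lower for 5 of 17 and higher for 0, with a median of -0.10 (camera adjusted p = 0.0212, and adjusted p = 0.536 with an estimated correlation), and the call was lost without KO replicate 2 (camera adjusted p = 0.0558). With the trends on GC content and length removed, 6 clock genes were lower and 3 higher. Of 10 Hedgehog pathway genes, 4 were higher and 2 lower (camera adjusted p = 0.417): Boc and Gas1 rose by 0.78 and 1.07 (edgeR adjusted p = 4.30e-04 and 4.74e-03) and the transcription factor Gli2 fell by 0.94 (edgeR adjusted p = 2.42e-03). Cell cycle genes went both ways, 7 higher and 9 lower of 28, with a median of 0.28 while the test pointed lower (camera adjusted p = 0.805). Plk1 and Cdc20, which act in mitosis, were at 1.08 and 1.03, and Mcm2 and E2f1, which act in DNA replication and entry into S phase, at -1.08 and -0.69, all named after their values were seen. Of the 27 interferon-stimulated genes, 2 were higher and 4 lower, and of 17 collagens 3 were higher and 1 lower (camera adjusted p = 0.684 and 0.707). The collagen median was -0.06 while the test pointed higher, and 0.12 with the trends on GC content and length removed.

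Among genes with a mean of at least 100 counts, the highest fold change with T3 was that of Hsd3b6, a steroid dehydrogenase, which rose from 0.197 ± 0.0488 to 15.4 ± 0.963 CPM, a change of 6.28 (edgeR adjusted p = 5.44e-07). Stc1, a secreted glycoprotein, rose by 4.83 (edgeR adjusted p = 3.93e-05) and Olr1, a receptor for oxidised lipoprotein, by 4.64 (edgeR adjusted p = 4.16e-07). The lowest was that of Trim66, at -5.03 (edgeR adjusted p = 9.04e-09). The transcription factor gene Klf15 changed by -4.10 (edgeR adjusted p = 4.50e-07), Soat2, which esterifies cholesterol, by -4.06 (edgeR adjusted p = 4.34e-06) and the thioesterase gene Acot2 by -3.55 (edgeR adjusted p = 2.05e-07). Trim66, Klf15, Soat2 and Acot2 were not called between KO and WT (edgeR adjusted p = 0.0608, 0.819, 0.733 and 0.188).

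By the same test, 4652 of 15276 genes (30.5%) differed between KO+T3 and KO, 2555 higher and 2097 lower, with a median absolute log2 fold change of 0.685. The groups did not overlap in 48.3% of genes, where chance gives 10%. Adjusted over the list alone, the counts became 18 higher for growth factors, 1 higher for clock genes, 10 lower for cell cycle genes, 1 higher and 3 lower for interferon-stimulated genes, 5 higher for Hedgehog genes, 9 higher and 2 lower for glycolysis, 9 higher and 4 lower for hypoxia, 7 higher for proteases, 5 lower for p53 genes, 4 lower for thyroid hormone handling, 3 lower for transition regulators and 1 higher for endothelial markers, and were the same on the other lists. The share of calls that were higher was 54.9%, and 34.8% with scaling by library totals, which moved the median of all genes from 0.0283 to -0.108, and 44.3% with upper-quartile factors.

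Reversal asks how far the genes that differed in KO lay back towards WT in KO+T3. Of the 10544 genes called in KO versus WT, 2697 (25.6%) were called in the opposite direction with T3, 875 (8.30%) in the same direction and 6972 in neither. The reversed genes were 1392 of the 5192 that were lower in KO and 1305 of the 5352 that were higher. Among those lowest in KO, Cxcl5 stood at 3271 ± 2603 CPM in WT, 5.23 ± 0.906 in KO and 109 ± 9.37 in KO+T3, and Il6 at 213 ± 175, 0.429 ± 0.216 and 10.1 ± 1.86 CPM (SD, n = 3). Lum rose with T3 by 2.38 on the log2 scale (edgeR adjusted p = 0.0225), and Ogn from 0.880 ± 0.242 to 2.38 ± 0.520 CPM (edgeR adjusted p = 0.0190). Against WT they remained at -8.57 and -8.14. Both calls were lost by limma-voom (adjusted p = 0.239 and 0.204) and without single libraries: for Lum without KO replicate 1 or 2 or KO+T3 replicate 1 or 2 (edgeR adjusted p = 0.0530 to 0.0746), and for Ogn without KO replicate 1 or 2 or KO+T3 replicate 2 or 3 (edgeR adjusted p = 0.0509 to 0.0799). The call of Lum was also lost with the trends on GC content and length removed, at 2.16 (edgeR adjusted p = 0.0532). Among the genes highest in KO, Nptx1 fell by 1.19 with T3 (edgeR adjusted p = 1.75e-04), Dusp4 by 1.03 (edgeR adjusted p = 1.35e-03), Prrt4 by 1.64 (edgeR adjusted p = 1.52e-04) and the immune receptor gene Havcr2 by 1.29 (edgeR adjusted p = 6.89e-05).

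Over the genes called in KO, the slope of the change with T3 on the change in KO was -0.125, and the median gene was restored by a fraction of 0.163. Of the reversed genes, 1105 were no longer called against WT and 193 had passed it. Both comparisons use the KO libraries, which alone gives some opposite signs. The covariance of the log2 fold changes over all genes was -0.359, against -0.0483 on average in 50 simulated sets without an effect of T3. The correlation across genes, which are not independent replicates, was -0.286 against -0.0896. Independent calls would give 1603 genes in opposite and 1608 in the same direction. The KO libraries were too few to be split into parts with 2 libraries each, so part of the excess may come from the shared libraries. Without KO replicate 2, 1735 genes were reversed. Without KO replicate 1 or 3, 541 and 557 genes were called in the same direction. With scaling by library totals, 74.3% of the reversed genes had been higher in KO, against 48.4% here. With the trends on GC content and length removed, 2651 genes were reversed and 1230 called in the same direction. The slope was then -0.108, the median restored fraction 0.121 and the covariance -0.279. The GC trend with T3 ran opposite to that in KO: its median change was 0.23 at the lowest GC content and -0.12 at the highest. Part of the reversal may therefore come from these trends.

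**Figure D4:**
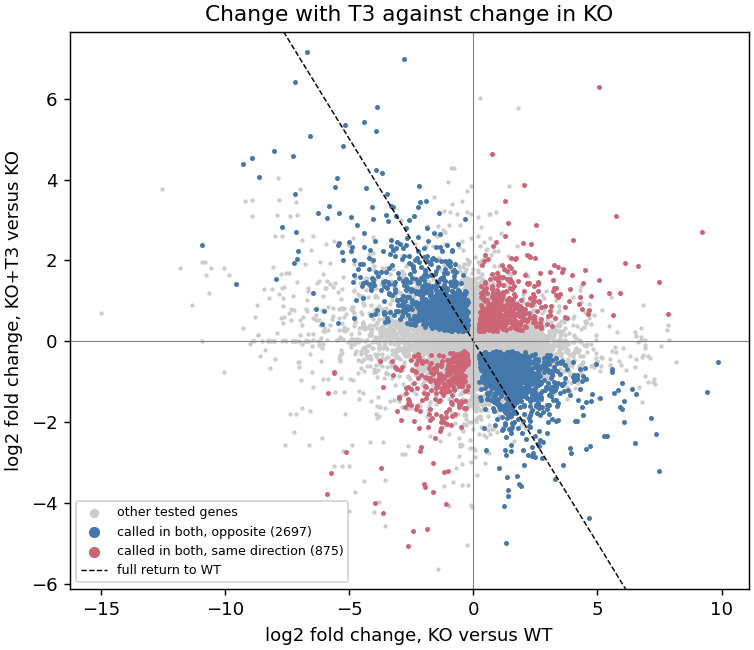
Log2 fold change of each tested gene in KO versus WT on the horizontal axis and in KO+T3 versus KO on the vertical axis. Blue points are the 2697 genes called in opposite directions, red points the 875 called in the same direction, and the dashed line marks a full return to WT.

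The comparison of KO+T3 with WT asks what difference remained with T3. The interferon, collagen, proteoglycan and hypoxia lists were lower than in WT here too, and the cell cycle list was higher. None of these lists held its call with an estimated correlation. All 27 interferon-stimulated genes were lower than in WT, with a median of -5.28 (camera adjusted p = 1.41e-41, and adjusted p = 0.0779 with an estimated correlation). Collagens were lower for 12 of 17 measured members and higher for 2, with a median of -1.90 (camera adjusted p = 5.36e-07, and adjusted p = 0.17 with an estimated correlation), or -2.75 with the trends on GC content and length removed. Krt14 and Krt5 moved with these groups as in KO, and keratinocyte markers were lower for 11 of 13 and higher for 0 (camera adjusted p = 4.79e-04, and adjusted p = 0.17 with an estimated correlation).

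Matrix glycoproteins and proteoglycans were lower for 20 of 26 and higher for 3, with a median of -1.08 (camera adjusted p = 9.83e-10, and adjusted p = 0.0569 with an estimated correlation). Collagen processing genes were lower for 11 of 17 and higher for 2 (camera adjusted p = 4.57e-03, and adjusted p = 0.323 with an estimated correlation). Inflammatory fibroblast genes were lower for 14 of 21 and higher for 5, with a median of -3.66 (camera adjusted p = 1.23e-03, and adjusted p = 0.531 with an estimated correlation), or a median of -2.61 without WT replicate 1. Antigen-presenting genes were lower for 6 of 7 (camera adjusted p = 1.85e-03, and adjusted p = 0.138 with an estimated correlation). Macrophage and myeloid markers were lower for 7 of 10 and higher for 1, with a median of -1.90 and no call (camera adjusted p = 0.0971). Hypoxia-responsive genes were lower for 13 of 17 and higher for 1 (camera adjusted p = 2.93e-05, and adjusted p = 0.17 with an estimated correlation). Wnt genes were lower for 9 of 16 and higher for 5 (camera adjusted p = 0.0104, and adjusted p = 0.17 with an estimated correlation). Unfolded protein and stress response genes were lower for 11 of 19 and higher for 5, with a median of -0.32 (camera adjusted p = 6.76e-04, and adjusted p = 0.313 with an estimated correlation). Myofibroblast genes, with 9 lower and 7 higher of 20 and a median of -0.15, were called lower as a set (camera adjusted p = 0.0234, and adjusted p = 0.323 with an estimated correlation). Cell cycle genes were higher for 27 of 28 and lower for 0, with a median of 1.22 (camera adjusted p = 1.83e-06, and adjusted p = 0.531 with an estimated correlation). Cholesterol genes were higher for 14 of 20 and lower for 3, with a median of 0.80 (camera adjusted p = 0.015, and adjusted p = 0.538 with an estimated correlation). Glycolysis genes, 9 lower and 4 higher of 19, and clock genes, 10 lower and 3 higher of 17, were also called lower (camera adjusted p = 0.0375 and 0.0365, and adjusted p = 0.559 and 0.426 with an estimated correlation). The clock call was lost without WT replicate 1 (camera adjusted p = 0.062) and the glycolysis call in the fit of the 2 groups alone, with a replicate block, and without WT replicate 2, KO+T3 replicate 2 or KO+T3 replicate 3 (camera adjusted p = 0.054 to 0.0726).

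At the lower end, Saa3 stayed at -14.33 against WT (edgeR adjusted p = 6.36e-06), or -11.84 without WT replicate 1. Shisa3 had 0 counts in KO+T3 and was at least 254-fold lower (edgeR adjusted p = 1.29e-03), a bound that again rests on WT replicates 2 and 3. Adamts15, a matrix protease gene, had 1 count over KO+T3 and was lower by a ratio of 2420 (95% counting interval 433 to 95500; edgeR adjusted p = 6.39e-07), and its fitted log2 fold change moved from -10.80 to -12.61 without KO+T3 replicate 3, which held that count. At the upper end, Cyp1a1, a target of the aryl hydrocarbon receptor, and Hsd3b6 had 0 counts in WT and were at least 427-fold and at least 285-fold higher in KO+T3 (edgeR adjusted p = 7.61e-09 and 2.03e-08). Fibcd1, an acetyl-binding receptor, rose by 8.02 (edgeR adjusted p = 1.17e-09). Klf9 and Thrb were higher than in WT by 1.29 and 1.66 (edgeR adjusted p = 1.93e-06 and 5.85e-06). Dio3 remained lower by a log2 change of -2.23 and Thra by -0.57 (edgeR adjusted p = 2.73e-04 and 4.88e-04). Hr was higher by 1.18 (edgeR adjusted p = 1.92e-03), a call that was lost against WT replicate 1 alone (edgeR adjusted p = 0.0669) and with the trends on GC content and length removed, where the change was 0.11 (edgeR adjusted p = 0.747).

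By the same test, 10026 of 15276 genes (65.6%) differed between KO+T3 and WT, 5297 higher and 4729 lower, with a median absolute log2 fold change of 1.06. The groups did not overlap in 69.3% of genes, where chance gives 10%. Of the genes called in KO, 8265 (78.4%) were called in the same direction here. Adjusted over the list alone, the counts differed by 1 for keratinocyte markers (12 lower), clock genes (4 higher), mitochondrially encoded genes (5 lower), Notch genes (7 lower) and growth factors (14 lower). Scaling by library totals moved the median of all genes from 0.0389 to 0.175.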

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

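Over the alternatives with every library, other than the 2-fold threshold, the count of called genes stayed at 9927 to 11323 in KO versus WT, 4541 to 5555 in KO+T3 versus KO and 9414 to 10795 in KO+T3 versus WT. DESeq2 called 10877, 4813 and 10396 and limma-voom 10550, 4771 and 10072, with 2805 and 2771 genes reversed. Leaving out each library of the 2 groups compared in turn gave 9804 to 10613, 3123 to 4447 and 9283 to 10056. KO+T3 versus KO was not counted without a WT library, though the groups share 1 estimate of the spread. Reversal ranged from 1735 genes without KO replicate 2 to 3216 without WT replicate 1. Without WT replicate 1, calls in the same direction also rose, from 875 to 1141, and KO calls moved from 10544 to 10613. That library correlated with WT replicates 2 and 3 at 0.971 and 0.973 in log2 CPM, against 0.988 between those. It enters KO+T3 versus KO only through the shared filter, scaling and spread. Which of these moved the count was not tested. With WT replicate 1 alone as WT, 9718 and 9253 genes were called and 2938 reversed. At a 2-fold threshold 5887, 1313 and 5317 genes remained and 592 were reversed, by the construction of that threshold. Adding a replicate block gave 10383, 4541 and 9916 called and 2663 reversed genes. Deviations of libraries that share a number correlated at -0.114 to 0.135, and those with different numbers at -0.116 to 0.112. Between WT and KO, shared numbers gave 0.0187 to 0.135 and different numbers -0.116 to 0.0349. Between KO and KO+T3, shared numbers gave -0.114 to 0.0268 and different numbers -0.0592 to 0.112. With 3 libraries per group these values neither show nor exclude a weak pairing. With the trends on GC content and length removed, 8307 of the 10544 genes called in KO versus WT were called in the same direction and 207 in the opposite one.

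Among named genes, Thra in KO versus WT turned from -0.11 to 0.162 with library totals. Hr, at 0.06 in the same comparison, was -1.277 with the trends on GC content and length removed, -0.335 against WT replicate 1 alone, and -0.14 to 0.307 over the left-out libraries. Dio2 in KO+T3 versus WT ranged from -0.854 without KO+T3 replicate 2 to -0.394 without WT replicate 3. The cause of these shifts was not tested. Among the 100 gene results run under the alternatives, no other turned direction. DESeq2 gave no adjusted p for Saa3 against WT in either comparison or for Lcn2, and Shisa3 was not tested under the filter of at least 1 CPM.

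Lists were called 16, 14 and 15 times in the 3 comparisons at the preset correlation. With an estimated one they were called 1, 0 and 0 times. Calls were also lost where the estimate lay below the preset 0.01. In KO versus WT it was 0.00958 for Wnt genes and -0.0973 for antigen-presenting genes. A lost call therefore does not by itself show that members moved together. Lists were called 22, 16 and 22 times without the low-count filter, and 20 times in KO versus WT without WT replicate 3. In KO+T3 versus KO this added glycolysis (0.00377, and 0.031 without KO replicate 2 and 0.0157 without KO+T3 replicate 2) and hypoxia (0.0344) without the filter, and proteases in the fit of the 2 groups alone (0.0348; camera adjusted p). In KO+T3 versus WT calls were gained without the filter for basement membrane, TGF-beta, YAP and TAZ, transition regulator, p53, fatty acid and macrophage lists (camera adjusted p = 0.00352 to 0.0311), for basement membrane genes without WT replicate 1 or 3 (camera adjusted p = 0.00135 and 0.0321) and for fatty acid genes without WT replicate 2 (camera adjusted p = 0.0451). The mitochondrially encoded list, called lower in KO versus WT at a median of -0.82, turned to 0.46 with the trends on GC content and length removed, and camera was not run on that fit. The lists whose camera test turned direction were not called. In KO versus WT the camera adjusted p was 0.84 without the low-count filter for cholesterol genes, with a range of 0.77 to 0.993 over the left-out libraries. For stress response genes it was 0.829 without the filter, 0.974 in the fit of the 2 groups alone and 0.894 to 0.978 over left-out libraries. TGF-beta genes ranged from 0.738 to 0.977, YAP and TAZ targets from 0.665 to 0.977 and fatty acid synthesis from 0.665 to 0.861 (camera adjusted p). In KO+T3 versus KO the fit of the 2 groups alone gave 0.746 for Wnt genes and 0.837 for cell cycle genes, and left-out libraries gave 0.473 to 0.907 for collagens and 0.805 to 0.995 for Schwann cell markers (camera adjusted p). In KO+T3 versus WT, immediate early genes had 0.997 in the fit of the 2 groups alone, 0.970 with a block and 0.304 to 0.956 over left-out libraries, and thyroid hormone handling genes 0.695 to 0.984 (camera adjusted p). In medians, removing these trends also turned KO+T3 versus WT from -0.39 to 0.67 for mitochondrially encoded genes, from -0.29 to 0.06 for oxidative phosphorylation, from 0.39 to -0.08 for immediate early genes, from -0.11 to 0.06 for growth factors and from 0.28 to -0.11 for endothelial markers. In KO+T3 versus KO it turned thyroid hormone handling, glycoprotein, adipocyte and Schwann cell medians, all between -0.20 and -0.05, to 0.01 to 0.06. The cause was not tested. Genes near the lower end of the counts are limited by depth: Dio2 had 16 to 84 counts per library.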

Other observations

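Gene groups without a call as a set held members that changed in opposite directions in KO, named here after their values were seen. Over all 15276 tested genes, 5352 were higher and 5192 lower in KO, so members in both directions do not set these lists apart. Of 19 basement membrane genes, 6 were higher and 10 lower (median -0.77, camera adjusted p = 0.249, and 0.0097 without WT replicate 1): the laminin chains of epithelia Lama3 and Lamb3 changed by -6.70 and -5.37 and the type IV collagens Col4a1 and Col4a2 by 2.15 and 2.40. Of 21 TGF-beta genes, 9 were higher and 9 lower (median -0.21, while the test pointed higher; camera adjusted p = 0.925), with the ligands Tgfb1 at 4.12 and Tgfb2 at -3.38. Notch genes, 4 higher and 6 lower of 13 (median -0.09, camera adjusted p = 0.649), had the ligands Dll4 and Jag2 at -3.97 and -3.87 and the targets Hey1 and Hey2 at 2.97 and 2.79. Adipocyte genes, 3 higher and 3 lower of 8 (median -0.11, while the test pointed higher; camera adjusted p = 0.821), had the regulators Pparg and Cebpa at 3.70 and 2.07 and the lipid handling genes Fabp4, Cd36 and Lpl at -3.35, -3.17 and -2.09. Regulators of the epithelial-mesenchymal transition were higher for 3 and lower for 4 of 12 (median -0.25, while the test pointed higher; camera adjusted p = 0.649). Matrix proteases and inhibitors were higher for 7 and lower for 12 of 24 (camera adjusted p = 0.112, but 0.0377 without the low-count filter, 0.0244 without WT replicate 1 and 0.0467 without WT replicate 3), growth factors for 10 and 16 of 33 (camera adjusted p = 0.0903, but 0.0223 without the filter and 0.0368 without WT replicate 3), and thyroid hormone handling genes for 6 and 3 of 13 (camera adjusted p = 0.717). Immediate early genes were higher for 3 and lower for 9 of 17 (camera adjusted p = 0.0814, but 0.0398 with a replicate block, 0.0193 without the filter and 0.0122 without WT replicate 3), with 6 higher without WT replicate 1. Clock genes were higher for 4 and lower for 7 of 17 (camera adjusted p = 0.428), and textbook T3-responsive genes for 4 and 4 of 11 (median 0.06, while the test pointed lower; camera adjusted p = 0.656). YAP and TAZ targets were higher for 7 and lower for 5 of 14, cholesterol genes for 8 and 7 of 20, fatty acid genes for 5 and 6 of 13 and stress response genes for 8 and 9 of 19 (camera adjusted p = 0.821, 0.933, 0.821 and 0.925). Several of these depend on the trends on GC content and length. With both removed, the median turned from 0.34 to -0.43 for YAP and TAZ targets (4 higher, 6 lower), from 0.09 to -0.39 for fatty acid genes, from 0.06 to -0.15 for T3-responsive genes and from -0.18 to 0.22 for stress response genes (10 higher, 7 lower). It moved to -1.58 for basement membrane genes (5 higher, 11 lower), -0.67 for Notch genes, -0.72 for adipocyte genes and -1.38 for immediate early genes.

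Markers of other cell types were also measured. Of 10 endothelial markers 3 were higher and 2 lower in KO (camera adjusted p = 0.821), with Cdh5 at 1.48 and Kdr at 0.07 without a call, where WT replicate 1 held 5.13 CPM of Kdr against 11.5 and 13.4 in WT replicates 2 and 3. Of the same markers 5 were higher without WT replicate 1, where the median was 1.01 instead of 0.61. Pericyte and smooth muscle markers were higher for 2 and lower for 4 of 8 (camera adjusted p = 0.0903, but 0.0487 without the low-count filter), with Cspg4 at 4.23 and Mcam at 0.73, and Ndufa4l2, named after its value was seen, at -7.68. Skeletal muscle markers were higher for 1 and lower for 5 of 7 (camera adjusted p = 0.114, but 0.0287 without the filter), with Acta1 at -0.96 and Myh3 at -2.74, and Schwann cell markers higher for 3 and lower for 1 of 5 (camera adjusted p = 0.857), with Mbp at -2.22, and 1 higher and 1 lower with the trends on GC content and length removed. Of 2 melanocyte markers 1 was lower, Mitf at -1.93, and Pmel was at -0.64 without a call. None of 11 lymphocyte markers was measured above the filter. With T3, Csf1r, the macrophage colony-stimulating factor receptor, rose by 3.48, named after its value was seen, and Cd14 by 1.63. Of 4 measured sex-linked genes, all Y-linked, 0 were called in any comparison, but without WT replicate 1, which had 0 counts of them, 4 were lower in KO, with a median of -1.11, and 3 were lower in KO+T3 than in WT. Cdh1 had 60, 5 and 1 counts in the WT libraries, Epcam 93, 5 and 1 and Krt8 309, 1 and 3, the reverse order of Krt14 and Krt5, named after their values were seen.

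The breadth of the difference between KO and WT was weighed after the result was seen, and the tests on T3 and on GC content were also written after. Keratinocytes or carcinoma cells in the WT libraries may add to it and stay open. WT replicate 1 lies 0.386 of the way to KO for Krt14 and 0.396 for Krt5. Over the called genes it had a slope of 0.0241 (SE 0.00692, from leaving out each chromosome in turn). That slope rests on 1 library, which held the most Krt8, Epcam and Cdh1, so it excludes nothing. Copy number differences could act on neighbouring genes together. Windows along the chromosomes explained 5.4% of the variance beyond shuffled order. That share does not exclude them, since a shift of whole windows can be small beside the spread between genes within a window. A bias on GC content or length was weighed by removing both trends. Then 78.8% of the called genes were still called in the same direction and 729 of 10544 changed sign. If the difference came from missing T3 that 48 h of T3 puts back, the slope of the T3 change should be near full return. It was -0.125 (SE 0.00554, again over chromosomes and not libraries), against -0.0161 without an effect of T3. Leaving out single libraries gave slopes of -0.152 to -0.117, and effects of longer T3 lack were not tested. Differences between the animals or lines other than Dio2, such as the one in Xist in WT replicate 1, stay open, since the labels leave genotype and animal inseparable.

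Regrouping the 6 libraries of a comparison in all 10 ways gave as many called genes only in the real grouping, 1 of 10 splits in each comparison, with 0 as the highest count among the others. That is too few splits for a share under 0.05. At unadjusted p below 0.05 the other splits reached at most 287 genes in KO versus WT, 914 in KO+T3 versus KO and 452 in KO+T3 versus WT, against 10904, 6310 and 10509. Every other split mixed libraries of both groups, so the group difference widened its spread and kept its counts low. The regrouping therefore decides nothing about chance.

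A lysosomal programme was tested after Rragd, Fnip2 and Atp6v1b2 had been seen to fall with T3 by 2.66, 2.78 and 1.89, together with Trib3, Ddit3, Chac1 and Asns. Rragd, Fnip2 and Atp6v1b2 are targets of the transcription factors TFEB and TFE3, so a lower activity of those factors would lower their other targets. Of 36 measured targets that had not been seen, 25 were lower with T3 and 0 higher, with a median of -0.46 (camera p = 0.0102 with an estimated correlation). The interval of that median over list members, not libraries, was -0.77 to -0.31. With the trends on GC content and length removed the median was -0.42. In KO the same list had 25 higher and 6 lower members and a median of 0.68 (camera p = 0.139 with an estimated correlation). The result may reflect a lysosomal programme that T3 lowers, though transcripts alone do not show the activity of the factors.

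NRF2 targets were tested after Nqo1, Gclm, Hmox1 and Srxn1, genes of the oxidative stress defence, had been seen at 5.07, 3.09, 4.01 and 3.26 in KO. Of 25 measured targets that had not been seen, 20 were higher in KO and 3 lower, with a median of 1.29 (camera p = 0.036 with an estimated correlation), which could come from higher NRF2 activity in the KO cells. If that rise came from missing T3 that 48 h of T3 puts back, the list should fall with T3. With T3, 13 members were instead higher and 0 lower, with a median of 0.45 (camera p = 0.0402 with an estimated correlation), and Hmox1 alone of the genes first seen fell, by 0.88. That argues against a rise that 48 h of T3 puts back, and effects of longer T3 lack were not tested. The p-values of the NRF2 list were not adjusted either, and it too was chosen from members seen in these libraries. In KO versus WT, interferon and myofibroblast genes had smaller unadjusted values (camera p = 0.00676 and 0.00306 with an estimated correlation). Neither of those lists was called once adjusted.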
